A study of Mus musculus with 3 samples.

How the data were processed

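Dendritic cells were sorted by the submitters as lineage-negative, CD11c-positive, MHC class II-high cells and profiled by CITE-seq, which counts messenger RNA and antibody tags in the same droplet. The 3 groups were the inguinal lymph node of wildtype C57BL/6 mice (control node), the inguinal tumor-draining lymph node (TDLN) and the tumor of mice in which Braf and Pten were altered in melanocytes with 4-hydroxytamoxifen. Nodes were digested with collagenase and DNase, and the tumor digest also held hyaluronidase. Each group had 2 mice, told apart by hashtag antibodies within 1 sequencing sample, so group and sample cannot be told apart. The labels do not say whether the TDLN and the tumor came from the same animals. An age was given for the control mice only, and a time after induction for the TDLN and tumor mice only. Any difference in age or induction between the control node and the other groups therefore cannot be told apart from group.

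The deposited matrices held UMI counts, per the submitters' processing notes from Cell Ranger 6.0.1 with the mm10 reference, and all stored values were whole numbers. Each matrix held 32285 genes, 12 antibody tags and 2 hashtags, and 3 of the tags were isotype controls with 1 UMI in all. Gene positions were taken from GENCODE vM21 on GRCm38 (mm10) for 32158 genes, 99.6% of those in the matrices. Total gene UMIs per mouse were 42674475 and 44738682 in the control node, 57432606 and 50063966 in the TDLN, and 92819199 and 68214453 in the tumor. Intervals and floors cover counting error only.

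Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, 27927 of 30612 barcodes. Scrublet, run in scanpy 1.11.5 on each group with an expected rate of 0.05, gave automatic thresholds that called 0% to 2.18% of the cells of a mouse, so 1 score limit of 0.2 was used for all and 898 cells were removed. The 27029 cells used were scaled to 10000 counts, log-transformed, reduced to 2000 variable genes (leaving out Cd63 and 5 metabolic lists) and 30 principal components, joined to 20 neighbours and clustered with leidenalg 0.10.2 at resolution 1. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and R 4.3.3.

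The deposited files hold no cell types, so class names were rebuilt from marker lists and may differ from the submitters' classes. A cluster took the class with the most markers among its top 10 genes by fold, then with the most enriched markers. At least 4 markers had to be in a share of at least 0.2 of its cells and 1.5-fold above other cells, and clusters that missed this stayed unnamed. The names end in -like for that reason. The marker lists covered cDC1, cDC2, mregDC (mature dendritic cells enriched in regulatory molecules), pDC, Langerhans, cycling, monocyte, macrophage, B, plasma, T, NK and ILC, and endothelial cells.

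Counts were summed per mouse and class, with at least 20 cells per mouse. The 3 groups entered 1 fit per class with edgeR 4.0.16 (quasi-likelihood, TMM normalization, filterByExpr), and Benjamini-Hochberg adjusted p at or below 0.05 was called a change. CPM values (edgeR cpm) use the TMM-scaled library size and are given as mean ± SD over 2 mice per group, and log2 changes are given ± SE. The comparisons of CPM between cell classes for Bpifa2, Smr3a and Ifi202b use the plain library size. The mregDC-like cells were also compared with pooled cDC1-like and cDC2-like cells in 6 mice, with mouse as a block, for Cd63 and the genes of those 5 lists (sterol, fatty acid, LXR and efflux, glycolysis and hypoxia, lactate), which took no part in the clustering. Whether a change differed between classes was tested as an interaction with mouse as a block. Antibody tags were centred log-ratio (CLR) transformed over the 9 targets, averaged per mouse and tested with limma 3.58.1. Shares of cells were compared by a two-sided exact permutation test, which cannot go below 0.333 with 2 mice against 2.

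Gene lists were compared with all other genes by camera (limma, prior count of 2) at a preset correlation of 0.01. They were tested again with a correlation estimated from the data, which is given as the adjusted p with an estimated correlation. fry tested whether a list moved on its own. The 19 lists were sterol, fatty acid, LXR and efflux, glycolysis and hypoxia, lactate, regulatory, costimulation and maturation, migration, interferon response, MHC class II, MHC class I, inflammatory, pattern recognition, phagocytosis, Wnt and TGF-beta, cell cycle, dissociation stress, unfolded protein, and NRF2.

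Named genes followed a rule. They were the 10 largest rises and 10 largest falls among genes with adjusted p at or below 0.05, a mean of at least 30 CPM in the higher group and no overlap between the mice of the groups, leaving out immune receptor segments, mitochondrial, ribosomal protein, hemoglobin and sex-linked genes and unnamed models. Up to 10 passing members of each list were added, as were Cd63, Srebf2, Hmgcs1, Ido1, Cd274, Ccr7, Fscn1, Il12b and all members of the 5 metabolic lists in the comparison of classes. A fold against a group with no count uses a floor of 3 counts over the group. Groups, comparisons, marker and gene lists, this rule and all alternatives except those named as later additions were set before the data were examined, and the limits for naming clusters and for doublets were set after.

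The procedure was tested on simulated data with 200 changed genes, all with a mean of at least 20 CPM. It recovered 99% to 100% of the 2-fold changes, and 7.01% to 11.9% of calls were false. Recovery of changes in genes below that level, or with as many changed genes as the data held, was not tested. Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, hashtag number as a replicate block, a filter of 200 genes and 20% mitochondrial UMIs, no doublet removal, resolution 2, a hashtag rule of at least 10 UMIs and 3 times the other tag, tag counts scaled to the tag total of each mouse (log2), dendritic classes as the denominator of shares, and each mouse left out. Fits on single clusters were later additions. No comparison between groups was paired, as the labels do not say that a hashtag number marks a shared animal or day.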

Results

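Messenger RNA and 9 surface proteins were measured in sorted dendritic cells from 6 mice, 2 each for the control node, the TDLN and the tumor. The matrices held 4123 and 4007 barcodes for the control node, 5341 and 4845 for the TDLN, and 6572 and 5724 for the tumor. After filtering, 3701, 3526, 4914, 4411, 5765 and 4712 cells remained in that order. The median depth of these cells was 9550 and 10928.5 gene UMIs in the control node, 9471 and 9190 in the TDLN, and 13360 and 12091.5 in the tumor. All 6 cell populations passed a gate for CD11c and high MHC class II, which sets part of every share of cells given here.

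The make-up of the gate was compared first, to ask how the dendritic cell classes were spread over tissues. Of the cells used, 8084 were mregDC-like, 7468 cDC2-like and 3936 cDC1-like. The cDC2-like share was 47.1% ± 5.68 in the control node, 16.9% ± 2.49 in the TDLN and 24.1% ± 4.12 in the tumor (SD, 2 mice per group). The mregDC-like share was 21.8% ± 9.90, 37.4% ± 13.7 and 27.2% ± 14.0 in the same order, and the cDC1-like share was 12.1% ± 0.798, 13.4% ± 4.49 and 17.6% ± 2.21. By exact two-sided permutation test no share could pass, since 0.333 is the smallest p that 2 mice against 2 allow. The p was 0.333 for the cDC2-like share in both comparisons, where the mice of the groups did not overlap, which chance gives in 33.3% of splits. It was 0.667 for the mregDC-like share in both, and 1 and 0.667 for the cDC1-like share. Over the dendritic classes alone, the mregDC-like share was 34.1% and 19.1% in the control node, 65.0% and 44.0% in the TDLN and 49.9% and 27.2% in the tumor. On that scale the mice of control node and TDLN did not overlap either.

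**Figure D1:**
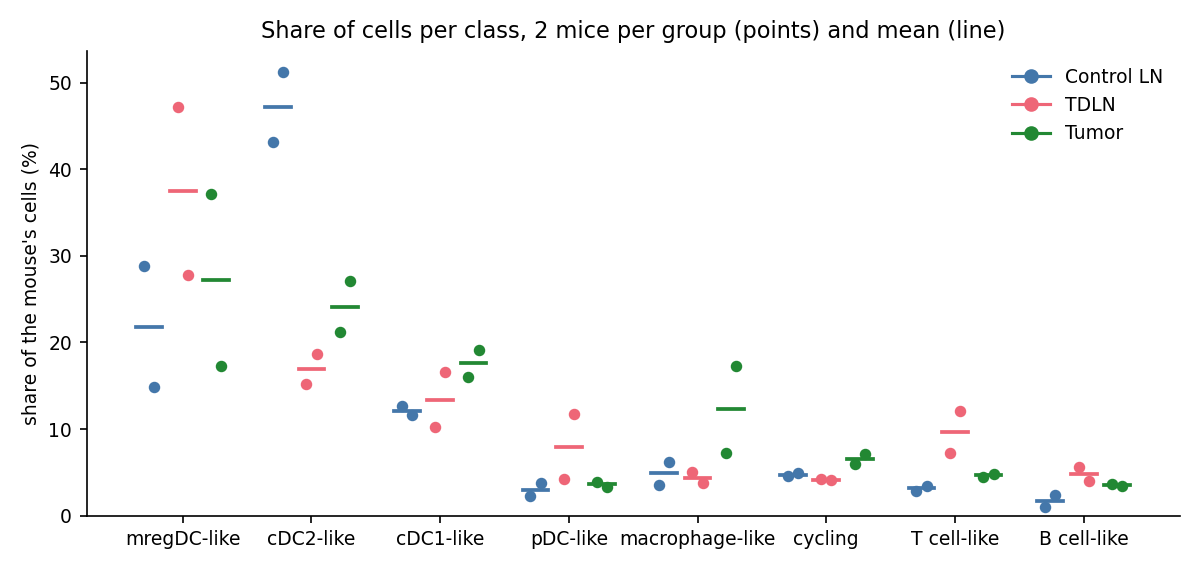
Share of the cells used in each of 8 classes (y axis, percent) for the control node, the TDLN and the tumor. Each point is 1 mouse, 2 per group, and each line is the group mean. The cDC2-like share was 43.1% and 51.2% in the control node against 15.2% and 18.7% in the TDLN.

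The clusters inside a class also differed between tissues. Cluster 6, marked by Apol7c and Clu, held 52.4% and 44.7% of the mregDC-like cells of the control mice, but 17.0% and 13.9% in the TDLN and 15.1% and 11.8% in the tumor. Cluster 4, marked by Myl7, Pla1a, Cd200 and Ccl22, held 1.41% and 2.49% in the control node, 29.7% and 32.5% in the TDLN and 31.8% and 22.2% in the tumor. Cluster 5, marked by Ccl22, Ccl17 and Aldh1a2, held 7.22% and 5.93%, then 28.1% and 23.2%, then 29.6% and 30.6%. In the cDC2-like class, cluster 10, marked by Hspa1a, Il1r2 and Tnfsf9, held 24.8% and 54.9% of the tumor cells but at most 0.938% in any node sample. Cluster 0 held 50.5% to 61.0% of the cDC1-like cells of every mouse.

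The series title asks about a sterol program driven by SREBF2 in a tolerogenic dendritic cell population, so mregDC-like cells were compared with the conventional dendritic cells of the same mice. The genes reported here took no part in the clustering. Cd63 (ENSMUSG00000025351, chromosome 10, 128900989 to 128912822 on GRCm38) was 87.0-fold higher in mregDC-like cells, at 755 ± 66.5 against 8.73 ± 1.35 CPM, and higher in 6 of 6 mice (log2 6.44 ± 0.07, adjusted p = 1.82e-10). Of the 26 genes of cholesterol synthesis and uptake, 19 were higher and 4 lower. Idi1 (chromosome 13, 8885501 to 8892451) was 10.1-fold higher at 129 ± 12.7 against 13.6 ± 6.47 CPM (log2 3.34 ± 0.20), and Hmgcs1 (chromosome 13, 119690379 to 119708260) was 3.57-fold higher at 77.8 ± 7.79 against 22.8 ± 9.46 CPM (log2 1.83 ± 0.18, adjusted p = 1.00e-05). The LDL receptor gene Ldlr (log2 1.91), Cyp51 (2.14) and Fdft1 (2.06) were higher too, each in 6 of 6 mice against the pooled cells. The lead of Ldlr did not hold over each class in every mouse. In separate fits per class, tumor mouse 2 had 52.9 CPM in mregDC-like, 62.4 in cDC2-like and 13.0 in cDC1-like cells. Ldlr in cDC2-like cells was at 12.1 and 12.3 CPM in the control node and 32.7 and 62.4 in the tumor. Srebf2 itself (ENSMUSG00000022463, chromosome 15, 82147181 to 82205379) did not pass, with 102 ± 9.60 against 94.1 ± 20.1 CPM, higher in 3 of 6 mice (log2 0.14 ± 0.13, adjusted p = 0.342). That result averages over tissues that differed. By separate fits per class, control mice had 109 and 97.3 CPM in mregDC-like, 68.3 and 62.9 in cDC2-like and 93.4 and 89.2 in cDC1-like cells. In the TDLN these were 95.75 and 84.5, 100 and 89.25, and 119 and 118. In the tumor they were 105 and 95.8, 97.2 and 117, and 122 and 123. The partner of the SREBF2 protein, Scap, was lower (log2 -0.64), as were Dhcr7, Ebp and Ggps1.

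The glycolysis and hypoxia list showed the opposite balance in that comparison, with 15 of 21 genes lower in mregDC-like cells and 4 higher. Hk2 was 7.80-fold lower at 16.5 ± 1.67 against 128 ± 15.9 CPM, and Pfkp, Gpi1, Eno1 and Pgam1 were lower with it. The hypoxia-linked genes of the list were split, with Adm 24.7-fold higher at 33.5 ± 3.82 against 1.38 ± 0.460 CPM and Ndrg1, Vegfa and Hif1a also higher, but Car9 (log2 -1.20), Pdk1 (-1.12), Ero1l, Ankrd37 and Bnip3 lower. Of 8 lactate genes, 5 were lower and 1 higher, among them Ldha (log2 -1.85) and the transporter gene Slc16a1 (log2 -2.21), while Ldhb was higher (2.08). Fatty acid synthesis was lower for 7 of 13 genes, including Elovl6 (log2 -2.56) and Fasn (-1.49), and higher for Acsl4. LXR and efflux genes were split 5 to 5, with Abcg1 higher (log2 1.49) and Lipa lower (-1.80). Over the 80 genes reported, 67 passed, 31 higher and 36 lower, and 76.7% of all 12830 genes tested passed as well. Against all genes, the sterol list was higher by camera (adjusted p = 0.0127; adjusted p = 0.469 with an estimated correlation) and the other lists did not pass (0.0515 for glycolysis and hypoxia, 0.130 for lactate and for fatty acid, 0.922 for LXR and efflux).

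**Figure D2:**
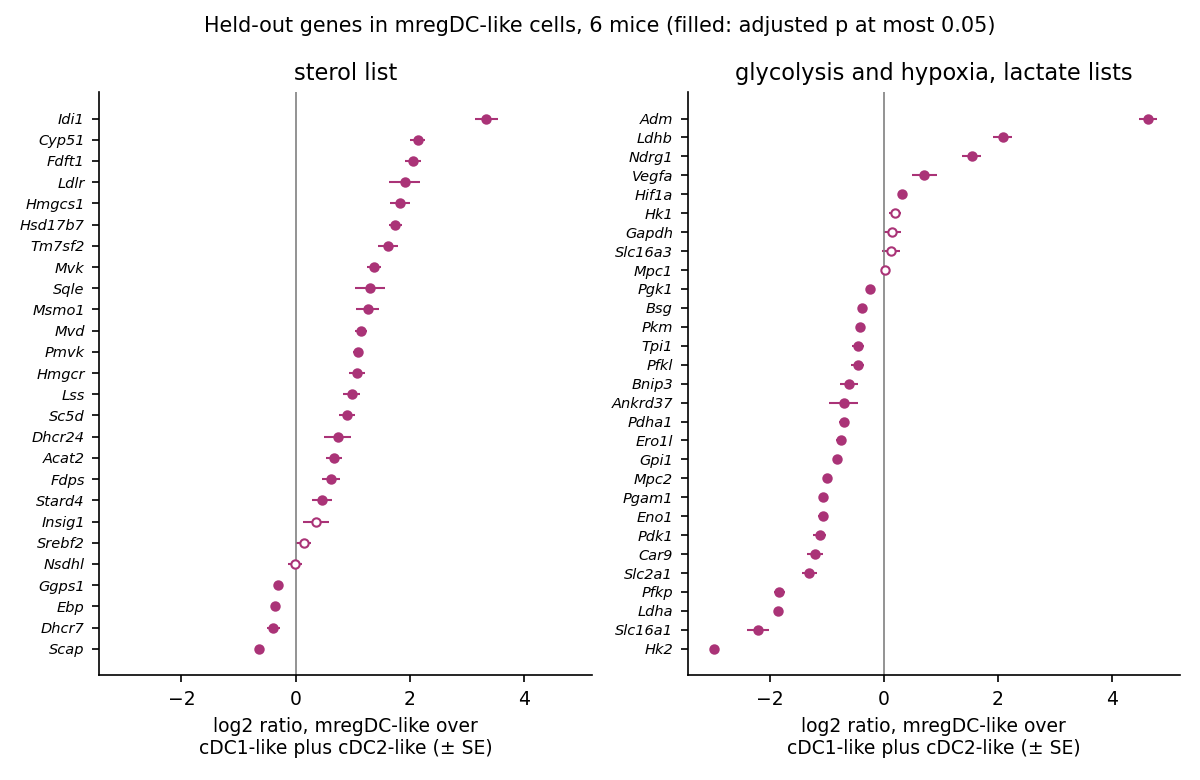
Log2 ratio of mregDC-like cells over cDC1-like and cDC2-like cells (x axis) for each gene of the sterol list and of the glycolysis and lactate lists, from 6 mice. Points are estimates, bars are SE, and filled points have an adjusted p at or below 0.05. Idi1 lies at 3.34, Srebf2 at 0.14 and Hk2 at -2.96.

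The comparison of mregDC-like cells between the TDLN and the control node asks how these cells differ where a node drains a melanoma. Ccl22, Ccl17, Cd80, Cd86 and Cd274 rose and Ccl5 fell by 1.33 on the log2 scale. The interferon (adjusted p = 3.49e-12), inflammatory (0.000655) and MHC class I lists (0.000863) shifted down by camera, each with an adjusted p = 0.237 with an estimated correlation. The sterol program did not move as a group. In all, 1451 genes rose and 1366 fell of 11897 tested, 970 of them by at least 2-fold.

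Costimulation and maturation genes went both ways in the TDLN, with 7 up and 7 down of 17 (camera adjusted p = 0.782), and regulatory genes did not pass as a list, with 7 up and 3 down of 21 (0.457). Cd80 rose 4.41-fold to 95.8 ± 0.757 from 22.3 ± 3.70 CPM, Cd86 rose 3.20-fold to 223 ± 27.5 from 70.8 ± 12.1 CPM, and Tnfsf4, Cd70 and Tnfsf9 rose by 3.91, 2.60 and 1.58 on the log2 scale. Among regulatory genes Cd200 rose 3.63-fold to 362 ± 2.29 CPM, Ebi3 rose by 1.75 and Pdcd1lg2 by 1.13. Cd200 marked cluster 4, which held more of the class in the TDLN than in the control node. Cd274, which codes for PD-L1 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), rose to 156 ± 16.9 from 87.0 ± 14.2 CPM (log2 0.87 ± 0.13, adjusted p = 0.000505). In cluster 6 alone Cd274 also rose (log2 1.21 ± 0.15). Il12b (chromosome 11, 44400063 to 44414033) fell by 0.94 to 30.5 ± 6.98 from 58.2 ± 10.0 CPM, Il15 fell by 0.91 and Il27 fell by 2.64. Ido1 stayed near the detection limit at 1.15 ± 0.536 against 0.959 ± 0.697 CPM (adjusted p = 0.744). Relb fell by 0.74, Havcr2 by 1.41 and Itgb8 by 1.35.

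Chemokine and migration genes went both ways. Ccl22 rose 5.22-fold to 2860 ± 315 from 546 ± 148 CPM and Ccl17 rose 4.80-fold to 705 ± 236 from 148 ± 17.0 CPM, while Ccl5 fell by 1.33 to 3793 ± 430 from 9558 ± 1848 CPM and Cxcl9 fell by 2.11. Ccl22 marked clusters 4 and 5 and Ccl17 marked cluster 5, which held more of the class in the TDLN than in the control node. The make-up of the class can therefore add to both rises. Fscn1, the fascin gene of mature dendritic cells (chromosome 5, 142960343 to 142973185), rose to 2077 ± 139 from 1298 ± 27.0 CPM (log2 0.68 ± 0.09, adjusted p = 0.00015), and Ccr7 did not pass (log2 -0.15 ± 0.09, adjusted p = 0.228). Among genes that met the naming rule (at least 30 CPM, no unnamed models), the largest rise was the myosin light chain gene Myl7. Myl7 (ENSMUSG00000020469, chromosome 11, 5896637 to 5898782) rose 260-fold to 105 ± 3.76 from 0.354 ± 0.158 CPM. Myl7 marked cluster 4, and in cluster 6 alone it rose as well (log2 5.67 ± 0.84). Mylk, Htr7, Pla1a, Dll4 and the transcription factor gene Ikzf4 followed, with Ikzf4 at 92.0 ± 5.19 against 18.1 ± 3.09 CPM.

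The interferon response list had 22 of 23 genes lower in the TDLN, with a median log2 change of -1.89 (camera adjusted p = 3.49e-12; adjusted p = 0.237 with an estimated correlation). Rsad2 fell by 2.58, Irf7 fell by 2.47, Isg15 fell by 1.98 and Ifi27l2a fell by 2.79, the last to 36.5 ± 11.9 from 260 ± 69.7 CPM. Inflammatory genes fell for 9 of 17 (0.000655; 0.237 with an estimated correlation), including Ptgs2, Il18, Tnf and Cxcl1. Ccl4 and Ccl3 fell too, though their control values varied widely (15.0 ± 14.4 and 10.6 ± 8.34 CPM). Of 16 MHC class I genes 8 fell, among them H2-K1, H2-D1 and B2m (0.000863; 0.237), and 10 of 19 dissociation stress genes fell, among them Fos, Dusp1 and Atf3 (6.67e-05; 0.237). LXR and efflux genes fell for 6 of 12 and rose for 1 (0.00701; 0.298), with Npc2, Abcg1 and Lipa lower and Apoe higher. Cell cycle genes rose for 5 of 19 (0.00184; 0.320) and fatty acid genes for 4 of 13 (0.0166; 0.237), including Scd2, Elovl5 and Fads2.

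Of the sterol list, Hsd17b7 and Tm7sf2 rose and Hmgcr fell by 0.68, and 23 of 26 genes did not pass. Its median (-0.02) and its mean (0.06) differed in sign, the test pointed down, and camera gave an adjusted p of 0.802 (0.891 with an estimated correlation). fry gave p = 0.888 for a shift of the list in 1 direction and p = 0.000169 for change in either direction. Srebf2 (log2 -0.20 ± 0.10, adjusted p = 0.191), Hmgcs1 (-0.04 ± 0.12, 0.863) and Cd63 (-0.20 ± 0.09, 0.143) did not pass. Gapdh, Ndrg1 and Pgk1 rose and Vegfa fell by 1.43 in a glycolysis list that did not pass (0.521), and Mpc1 rose in a lactate list that did not pass (0.782; median -0.05, mean 0.00). The remaining lists did not pass either, at 0.0600 for migration, 0.0659 for pattern recognition, 0.0984 for phagocytosis, 0.156 for unfolded protein, 0.454 for NRF2, 0.782 for Wnt and TGF-beta, and 0.802 for MHC class II, in which H2-Eb2 and Ctss fell while H2-DMa and Ciita rose (median 0.01, mean -0.06, test down). Every marker list of a cell class had an adjusted p of 0.136 or more. No list in any class or comparison of tissues passed with an estimated correlation.

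Under the naming rule the largest falls were Bpifa2 (ENSMUSG00000042459, chromosome 2, 154008265 to 154016079) and Smr3a (ENSMUSG00000029280, chromosome 5, 88002549 to 88008534), at least 545-fold and at least 516-fold lower in the TDLN. Both are genes of salivary gland secretions, and a Bpifa2 UMI was found in 29.3% of control mregDC-like cells (median depth 7581) and in 28.7% of control B cell-like cells (median depth 3958), so the transcripts were not limited to 1 cell class. Without control mouse 1 the count of changed genes was 1387 and without TDLN mouse 1 it was 1805. The clusters that held most of the class differed between the groups, and in cluster 6 alone 1439 genes changed. Without cluster 4, 916 genes rose and 1020 fell. By the DESeq2 Wald test 1847 genes of the class changed.

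**Figure D3:**
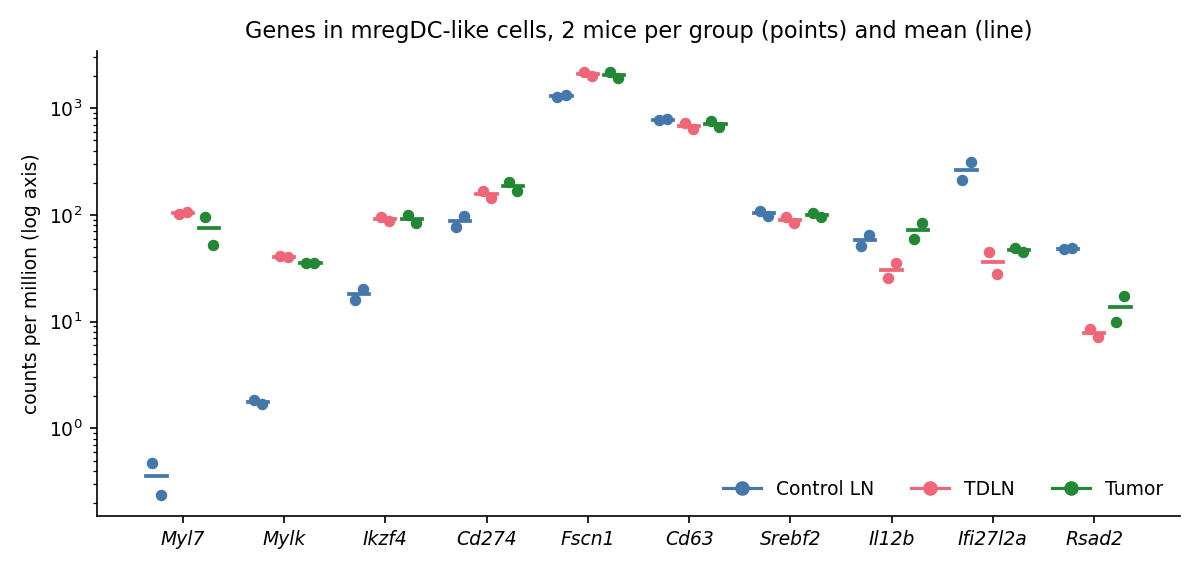
Expression of 10 genes in mregDC-like cells (y axis, CPM after TMM, log scale) in the control node, the TDLN and the tumor. Each point is 1 mouse, 2 per group. Myl7 lies at a mean of 0.354 CPM in the control node and 105 in the TDLN, and Srebf2 lies between 90.1 and 103 in the 3 group means.

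The comparison of mregDC-like cells in the tumor and in the TDLN asks how these cells differ between tumor and node. Lymph node tissue in the tumor samples stays open, so few changes cannot be read as a lack of effect of the site. By edgeR 5 genes were up and 20 down of 11897, with 1040 at an unadjusted p under 0.05. Without a filter on low counts 135 were up and 114 down of 20188, and without doublet removal 18 were up and 25 down. Il12b rose to 72.1 ± 17.6 from 30.5 ± 6.98 CPM (log2 1.25 ± 0.18, adjusted p = 0.0168), and it rose within cluster 12 (1.97 ± 0.29) and cluster 16 (0.64 ± 0.13) but did not pass within clusters 5 and 6 or in cluster 15 (log2 -0.86 ± 1.17, adjusted p = 0.970), and it was not tested in cluster 4. Cluster 16, marked by Il12b, held 4.83% and 6.86% of the mregDC-like cells of the TDLN and 7.86% and 12.6% of those of the tumor. Ier3 and the complement gene C1qb rose as well, C1qb from 2.19 to 7.88 CPM, and C1qb is a marker of macrophages. The ribosomal repeat transcript AY036118 fell by 1.88 to 1489 from 5494 CPM, Lars2 fell by 1.13, Polr2l fell by 0.72 and Uba52 fell by 0.60. AY036118, Lars2 and Uba52 also fell in B cell-like cells (log2 -1.50, -0.81 and -0.79), so these falls were not limited to dendritic cells. Cd274 (log2 0.25 ± 0.12, adjusted p = 0.609), Cd63 (0.07 ± 0.09, 0.844), Srebf2 (0.15 ± 0.10, 0.685), Hmgcs1 (0.10 ± 0.12, 0.832), Ccr7 (0.02 ± 0.08, 0.982) and Fscn1 (-0.02 ± 0.09, 0.977) did not pass.

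By list, interferon response genes shifted up in the tumor although none passed singly (camera adjusted p = 1.19e-06; adjusted p = 0.346 with an estimated correlation; 5 of 23 adjusted over the list alone). Dissociation stress (0.0002), inflammatory (0.000893), phagocytosis (0.00248), lactate (0.034), NRF2 (0.034) and MHC class II genes (0.0429) also shifted up and cell cycle genes down (0.034). With an estimated correlation these 7 had adjusted p of 0.346 to 0.569. The sterol list did not pass (0.0554; 0.346 with an estimated correlation). Among the marker lists of other cells, the macrophage list shifted up most (3.13e-05; 0.214), with 1 gene of 8 passing and 5 adjusted over the list alone. Without TDLN mouse 1 the count of changed genes was 59 and without TDLN mouse 2 it was 12.

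In cDC2-like cells the same comparison of nodes found a sterol program that rose. Of 26 sterol genes 6 rose and none fell, and 12 rose adjusted over the list alone (camera adjusted p = 1.10e-06; adjusted p = 0.541 with an estimated correlation). Fdps rose 2.62-fold to 37.1 ± 3.38 from 14.2 ± 0.448 CPM, Srebf2 rose to 94.8 ± 7.87 from 65.6 ± 3.82 CPM (log2 0.53 ± 0.12, adjusted p = 0.0266), and Pmvk, Idi1, Sqle and Hsd17b7 rose with them. Hmgcs1 did not pass (log2 0.57 ± 0.18, adjusted p = 0.0777). The change of Srebf2 was lower in mregDC-like than in cDC2-like cells by a test of the difference (log2 -0.74 ± 0.14, adjusted p = 0.00814). Fatty acid genes rose for 5 of 13, including Fasn, Scd1 and Fads2 (4.99e-05; 0.541), and Ldha (log2 0.60 ± 0.11), Pfkp (1.07) and Slc2a1 (1.00) rose within lists that did not pass (0.097 for lactate, 0.0936 for glycolysis).

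Of 13 MHC class II genes 8 fell in these cells, including H2-Eb1, H2-Aa, H2-Oa and Cd74, the last by 0.43 on the log2 scale as it dropped to 17770 ± 1078 from 23952 ± 116 CPM (0.000518; 0.541 with an estimated correlation). Interferon genes fell for 10 of 24 and rose for 1 (7.09e-06; 0.541), with Stat1, Xaf1 and Ifit3 lower and Ifi205 higher. Dissociation stress genes fell for 6 of 19 and rose for 1 (0.00976; 0.591), and unfolded protein genes rose for 3 of 13 (0.0355; 0.550). Regulatory genes Socs3, Socs2, Il4i1, Pdcd1lg2 and Lgals1 rose and Axl fell by 2.58, while Ccl5 fell by 2.10 and Lyz2 fell by 1.77 to 551 ± 160 from 1885 ± 146 CPM. Cd209e rose 5.72-fold to 363 ± 87.0 CPM. Lpl fell by 2.18 and Cd36 fell by 2.06, and the direction of both turned with other cell filters or a finer clustering. The classes changed in size with the wider cell filter, no doublet removal, resolution 2 and the hashtag rule. Macrophage-like cells went from 1994 to 1552, 1531, 1526 and 1573 in that order. The cDC2-like cells went from 7468 to 8084, 7928, 6523 and 7921. Whether this turned the 2 genes was not tested. Cd63, Cd274, Ccr7 and Fscn1 did not pass.

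Ifi202b (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744) was at 49.6 ± 10.8 CPM in TDLN cDC2-like cells and had no count in the control node, at least 621-fold higher. Transcripts of other cells rose too, with T cell markers up for 3 of 6 (0.00351; 0.359), plasma cell markers for 2 of 3 (0.0162; 0.359) and pDC markers for 4 of 8 (0.0222; 0.737), though Trbc2 reached only 3.98 CPM from 1.23. In all, 703 genes rose and 627 fell of 12419 tested, 435 by at least 2-fold. Without a filter on low counts 1247 rose and 1194 fell, and without cluster 10 1072 rose and 1021 fell. With 1 mouse left out the count was 190 without control mouse 1, 208 without control mouse 2, 312 without TDLN mouse 1 and 670 without TDLN mouse 2.

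Between tumor and TDLN, 39 genes rose and 30 fell of 12419 tested in cDC2-like cells by edgeR. These numbers depended on the method and on which clusters were used, with 193 up and 98 down by the DESeq2 Wald test, 635 and 314 without a filter on low counts, 79 and 25 at resolution 2, and 6 and 49 without cluster 10. Inflammatory genes rose for 5 of 18, and for 12 adjusted over the list alone (camera adjusted p = 1.56e-08; adjusted p = 0.359 with an estimated correlation). Ccl4 rose 9.99-fold to 143 ± 49.8 from 14.3 ± 0.0931 CPM, Cxcl2 rose by 3.45 on the log2 scale to 29.6 ± 0.542 from 2.69 ± 0.176 CPM, and Ccl3 and Tnf rose with them. Trem1 had 1 count in the TDLN, and its ratio of 80.5 had a counting interval of 14.2 to 3201. Ccl17 rose 12.7-fold to 163 ± 66.2 CPM, and the decoy receptor gene Il1r2, Tnfsf9, Emp1, Lilr4b and AA467197 rose. The heat shock genes Hspa1a and Hspa1b rose 9.15-fold and 9.94-fold, within a dissociation stress list with 3 of 19 genes up (0.000717; 0.553), and the tumor digest held an enzyme that the nodes did not receive. H2-M2, Cd81, Adgre1 and Cxcl9 fell, as did Mmp12, whose direction turned with other cell filters or a finer clustering.

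No sterol gene passed over all genes, while 14 of 26 rose adjusted over the list alone (1.66e-08; 0.359 with an estimated correlation). Hmgcs1 was at log2 0.95 ± 0.17 (adjusted p = 0.0587) and Srebf2 at 0.17 ± 0.11 (0.585). Glycolysis and hypoxia (0.000263), cell cycle (4.40e-06), NRF2 (0.0115) and lactate genes (0.0140) shifted up and interferon genes down (3.95e-06). With an estimated correlation these 5 had adjusted p of 0.359 to 0.541. Without cluster 10, found almost only in the tumor, none of the 19 lists passed (adjusted p of 0.0807 or more; 0.868 for sterol and for inflammatory), while the sterol rise from the control node to the TDLN had 13 genes passing (1.92e-08; 0.122). The count of 69 changed genes was 36 without TDLN mouse 1, 4 without TDLN mouse 2 and 749 without tumor mouse 1.

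In cDC1-like cells of the TDLN, 336 genes rose and 377 fell of 11186 tested by edgeR. Without a filter on low counts 660 rose and 657 fell, by the DESeq2 Wald test 198 rose and 234 fell, and in cluster 0 alone 187 rose and 239 fell. Itgae, which codes for CD103, rose 6.08-fold to 95.2 ± 45.7 from 15.4 ± 1.27 CPM, and Abca3, Fabp5, Ifitm2 and Nmt1 rose. Nmt1 rose in T cell-like cells of the TDLN too (log2 1.14), so its rise was not limited to dendritic cells. Srebf2 rose to 119 ± 1.02 from 91.3 ± 2.99 CPM (log2 0.38 ± 0.07, adjusted p = 0.00828) and Dhcr24 rose, but the sterol list did not pass (0.301). Fatty acid genes Fasn, Acsl4, Scd1 and Scd2 rose, 4 of 13 (0.000419; 0.433 with an estimated correlation). Interferon genes fell for 5 of 23, including Stat1, Xaf1 and Bst2 (0.000419; 0.782), and dissociation stress genes for 7 of 19, including Egr1 and Jun (0.00236; 0.782). Markers of mregDC rose for 5 of 12 (0.000183; 0.455), with Fscn1 at log2 1.18 ± 0.21 and Ccl22 at 2.45 ± 0.33, and markers of cDC1 (0.0296; 0.522) and of T cells (0.0209; 0.455) shifted up as well. Fscn1 reached only 16.4 and 13.3 CPM in the TDLN, against 2175 and 1978 in mregDC-like cells. Ccl22 also rose in B cell-like (log2 4.49) and macrophage-like cells (4.99) of the TDLN, and the source of these transcripts was not tested. Cd63 (log2 0.74 ± 0.27, adjusted p = 0.13), Hmgcs1, Cd274, Ccr7 and Il12b did not pass.

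Ifi202b was at 71.8 ± 2.34 CPM in TDLN cDC1-like cells with 3 counts in the control node, a ratio of 360 with a counting interval of 123 to 1749, while its neighbours on chromosome 1 Ifi203, Mndal and Ifi207 fell by 3.05, 1.84 and 1.43. The count of 713 changed genes was 91 without control mouse 1, 139 without control mouse 2 and 180 without TDLN mouse 1.

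Between tumor and TDLN, 18 genes rose and 17 fell in cDC1-like cells by edgeR, but 139 rose and 81 fell without a filter on low counts, and 4 rose and 13 fell in cluster 0 alone. The chemokine genes Ccl4 (28.0 ± 0.555 from 5.17 ± 1.78 CPM) and Ccl3 rose within an inflammatory list with 6 of 12 up adjusted over the list alone (2.40e-08; 0.324 with an estimated correlation). Ifitm1 rose 10.6-fold to 151 ± 25.4 CPM and Ifitm3 and H2-T23 rose, while Nmt1, Btg1 and Uba52 fell. Nmt1, Btg1 and Uba52 also fell in B cell-like cells (log2 -0.67, -0.47 and -0.79), so these falls were not limited to dendritic cells. H2-T23 rose in pDC-like cells as well (0.55). Sterol genes shifted up with none passing over all genes and 5 adjusted over the list alone (6.41e-05; 0.835), dissociation stress genes shifted up (0.0383; 0.835), and interferon genes (0.00122; 0.835) and T cell markers (0.00133; 0.464) shifted down. Srebf2, Hmgcs1, Cd63, Cd274, Ccr7, Fscn1 and Il12b did not pass. Without TDLN mouse 2 the count of 35 changed genes was 17.

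The antibody tags gave the surface protein side of the same comparisons. On mregDC-like cells of the TDLN, CD274 was higher than in the control node by 0.75 CLR units (limma adjusted p = 0.00214), as its gene was, and CD63 did not pass (-0.08, adjusted p = 0.724). The tag for MHC class II was lower by CLR (-0.50, adjusted p = 0.0381) but not when scaled to the tag total (0.705). On mregDC-like cells limma gave all 9 tags the same SE (0.176), so these p-values rest on a spread pooled over tags. The MHC class II tag itself varied more, at 3.89 ± 0.385 in the TDLN and 4.39 ± 0.274 in the control node (SD). On cDC1-like cells that tag did not pass by CLR (-1.05, adjusted p = 0.0689) but passed when scaled to the tag total (log2 -1.12, 0.0158). On cDC2-like cells it passed neither by CLR (-0.84, 0.126) nor when scaled (0.165). CD103 was higher in the TDLN on cDC1-like cells (1.42, adjusted p = 0.0139) and on cDC2-like cells (0.37, 0.0197). CD63 was lower on cDC1-like cells (-0.36, 0.0330). Itgae, the CD103 gene, rose in all 3 dendritic classes (log2 3.28 in mregDC-like, 3.75 in cDC2-like and 2.60 in cDC1-like cells). Scaled to the tag total, CD274 on mregDC-like cells and both CD103 calls passed and CD63 did not (0.555). CD172a, CD274 and CD11b passed on cDC2-like cells with that scaling (limma adjusted p = 0.0490 each) but not by CLR. With that scaling CD103 also passed on mregDC-like cells (log2 1.54, limma adjusted p = 0.0169), where it did not pass by CLR (0.30, 0.301). Its medians there overlapped, at 21 and 22 UMIs per cell in the TDLN and 17 and 28 in the control node. The tag total includes the MHC class II tag, with medians of 3454 and 6155.5 against 10506 and 7508. This CD103 call therefore cannot be told apart from a change of the total.

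No tag passed between tumor and TDLN on mregDC-like cells (limma with the same pooled SE, 0 of 9 tags at an unadjusted p under 0.05). On cDC2-like cells CD197, the CCR7 protein, was higher in the tumor (0.72, adjusted p = 0.00372), CD103 (0.25, 0.0326) and CD83 (0.26, 0.0494) were higher, and CD172a (-0.72, 0.00888) and CD274 (-0.67, 0.0494) were lower. Scaled to the tag total, CD103 (0.469) and CD83 (0.497) no longer passed there. On cDC1-like cells CD197 (0.63, 0.00358) and CD83 (0.23, 0.0178) were higher, and XCR1 (-0.44, 0.00775) and CD11b (-0.31, 0.00932) were lower. Of these 4 only CD197 passed when scaled to the tag total (0.00862), and CD83 (0.417), XCR1 (0.674) and CD11b (0.865) did not. The CD197 medians were at most 5 UMIs per cell in these classes. Leaving out 1 mouse changed the calls on mregDC-like cells in the TDLN, from 2 to 0 without TDLN mouse 1 and to 1 without control mouse 1. For cDC2-like cells the 1 call in the TDLN was lost without any of the 4 mice, and the 5 in the tumor became 1 and 2 without TDLN mouse 1 and 2 and 3 and 4 without tumor mouse 1 and 2. The 2 calls on cDC1-like cells in the TDLN became 0 without control mouse 1 or 2, and the 4 in the tumor became 1 without tumor mouse 1 and 2 without tumor mouse 2.

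**Figure D4:**
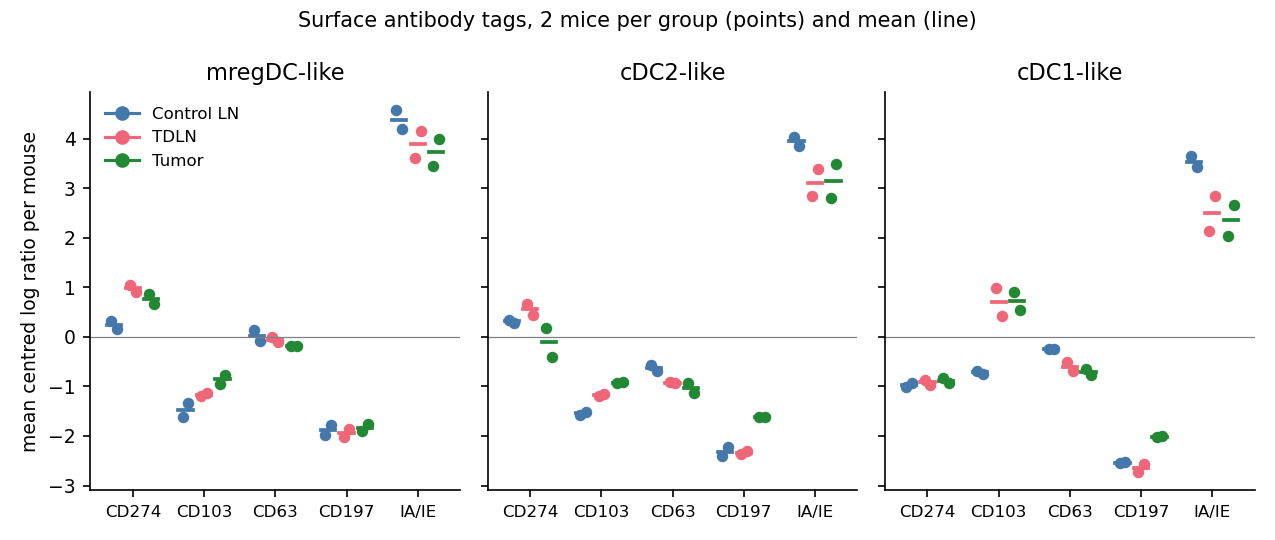
Mean CLR value per mouse (y axis, CLR units) of CD274, CD103, CD63, CD197 and MHC class II (IA/IE) on mregDC-like, cDC2-like and cDC1-like cells. Each point is 1 mouse, 2 per group. CD274 on mregDC-like cells lies at a mean of 0.24 in the control node and 0.98 in the TDLN.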

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

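The tests of expression by the dendritic cells, of free Ifi202b RNA, of an interferon effect on Ifi202b and of shared barcodes were chosen only after the result was seen.

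The change from the control node to the TDLN differed between classes by a test of the difference (edgeR interaction with mouse as a block). It did so for 1213 of 13198 genes between mregDC-like and cDC2-like cells and for 1205 of 12461 between mregDC-like and cDC1-like cells. Between tumor and TDLN the numbers were 41 and 6. Of 26 sterol genes 10 passed this test between mregDC-like and cDC2-like cells and 16 did not, and the list as a whole was not tested for the difference. The change was lower in mregDC-like cells for Srebf2 (log2 -0.74), Hmgcs1 (-0.64), Ldlr (-1.28), Hmgcr (-0.74), Pmvk (-0.79), Idi1 (-0.98), Fdps (-1.36), Fdft1 (-0.81), Sqle (-1.50) and Sc5d (-0.80). Fscn1 differed the other way (1.10). Against cDC1-like cells the change in mregDC-like cells was lower for Srebf2 (-0.58), Hmgcr (-0.59) and Cd63 (-0.96).

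Cells outside the 3 dendritic classes were present although the gate excluded lineage-positive cells, and some of their shares lay above those of both control mice. In the TDLN the mean share was 4.83% for B cell-like, 9.70% for T cell-like and 7.97% for pDC-like cells. In the tumor it was 3.52% for B cell-like, 4.65% for T cell-like, 6.57% for cycling and 12.3% for macrophage-like cells. The macrophage-like share of the 2 tumor mice, 7.22% and 17.3%, was 5.42% and 9.74% with the wider cell filter, 5.35% and 10.5% without doublet removal, 5.69% and 10.7% at resolution 2, and 5.80% and 10.7% with the hashtag rule, and in these 4 alternatives the first of them no longer lay above both control mice. NK and ILC-like cells did not exceed the control node in either tissue, nor did cycling and macrophage-like cells in the TDLN or pDC-like cells of 1 tumor mouse.

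The salivary gland transcripts Bpifa2 and Smr3a were found in control node cells and in no TDLN or tumor cell. Expression by the dendritic cells themselves was argued against, since B cell-like cells held 1.53 times the mean CPM of the dendritic classes (62.4 against 40.7), and a Bpifa2 UMI was seen in 26.0% to 36.7% of the cells of every named control class. Salivary gland RNA in the control samples is a candidate explanation, as 5 of 23 other genes of a fixed gland list (Pip, Cst10, Scgb2b27, Muc19 and Prb1) were above 3 counts there alone, with Muc19 and Prb1 at 4 counts each. Whether that RNA was free, taken up or attached to cells stays open, because Smr3a and Bpifa2 had 627 and 663 counts in mregDC-like cells but 839 and 373 in macrophage-like cells. A biological difference between wildtype and tumor mice was not tested and is confounded with the sequencing sample.

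Ifi202b was higher and its neighbours Ifi207 and Ifi213 were lower in the TDLN than in the control node in all 3 dendritic classes. Free RNA was argued against by a ratio of 0.00412 for Ifi202b between B cell-like and cDC1-like cells, and the lower interferon response of the TDLN stays open, as its test used the rise of Ifi202b itself (log2 8.36 in cDC1-like cells). Alleles that differ between the wildtype and the tumor mice are a candidate explanation, since 14 of 40 other genes changed the same way by at least 1 on the log2 scale in all 3 dendritic classes (of 169 changed the same way) lay within 1 Mb of another, against a median of 2 and a highest value of 12 in 1000 random lists. Leaving out neighbours of the same name family gave 8, reached by 27 of 1000 random lists. All 8 lay on chromosome 17, between 24693187 and 36038435, and Snhg9 lay within the span of Rps2. The others of the 14 were the pairs Lyz1 and Lyz2, Ifi27 and Ifi27l2a, and Ccl17 and Ccl22. The grouping was therefore not spread over the genome. Within 10 Mb of Pten 0 of 81 genes tested were among the 40, and within 10 Mb of Braf 1 of 73. Elsewhere the shares were 0.383% and 0.373%, so these counts are too small to decide. An effect of the tumor stays open and untested, as group, strain background, induction, any difference in age and sequencing sample cannot be told apart.

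Lymph node cell types such as B cell-like and T cell-like cells were found in the tumor samples. Misassigned barcodes were argued against, as a TDLN and a tumor matrix shared at most 14 barcodes. Lymph node tissue in the tumor samples stays open, because its test compared naive genes (median log2 change of 0.175 for B and 0.154 for T cell genes) inside clusters 9 and 11, which such genes mark. Lymphocytes in the tumor itself stay open as a biological explanation that was not tested.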

How the results depend on the processing

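Fits with cluster 4 or 10 left out and on cluster 0, 2 or 6 alone were chosen only after the data were seen, and the other alternatives before. The cause was not tested for any shift below, except that single clusters and mice left out use fewer cells or samples, and with 1 mouse in a group that mouse is assumed to vary like the other groups. With the dendritic classes as denominator the mregDC-like share differed by 27.9 and the cDC1-like share by 5.23 percentage points between TDLN and control node. The cDC2-like share differed by -20.8 at resolution 2 there, and by 10.7 without doublet removal, 10.8 at resolution 2 and 10.96 with the hashtag rule between tumor and TDLN. Counts of changed genes are given from TDLN against control node, then tumor against TDLN. Without a filter on low counts they were 2441 and 949 in cDC2-like and 1317 and 220 in cDC1-like cells, and 249 in mregDC-like cells of the tumor. With hashtag number as a block they were 2218 and 491 in cDC2-like and 1134 and 71 in cDC1-like cells, and 2835 and 30 in mregDC-like cells. Mice that share a hashtag number deviated together with correlations of -0.081 to 0.110 between control node and TDLN or tumor and of 0.154 to 0.263 between TDLN and tumor, so shared animals there are not excluded. The DESeq2 Wald test gave 1847 in mregDC-like and 432 in cDC1-like cells in the TDLN and 291 in cDC2-like cells in the tumor. No doublet removal gave 43 in mregDC-like and resolution 2 gave 104 in cDC2-like cells of the tumor. Cluster 6 alone gave 1439, cDC2-like cells without cluster 10 gave 2093, cluster 2 alone gave 14 in the tumor, and cluster 0 alone gave 426 and 17. In mregDC-like cells without cluster 4, 916 genes rose and 1020 fell in the TDLN, and 6 rose and 16 fell in the tumor. With an estimated correlation 0 of 19 lists passed by camera in all 3 classes and both comparisons. Scaled to the tag total, 4 and 3 surface proteins changed on cDC2-like cells and 1 on cDC1-like cells of the tumor. Leaving out 1 mouse gave 1387 to 2204 and 12 to 59 genes in mregDC-like, 190 to 670 and 4 to 749 in cDC2-like, and 91 to 582 and 17 to 38 in cDC1-like cells. It gave 63 to 65 genes between mregDC-like and other dendritic cells, and p of 0.534 to 0.910 for the sterol list in mregDC-like cells, which stayed unpassed in the other alternatives too (0.405 to 0.914). Surface protein calls ranged from 0 to 2 and 0 to 0 on mregDC-like, 0 to 0 and 1 to 4 on cDC2-like, and 0 to 2 and 1 to 4 on cDC1-like cells. In cDC2-like cells Lpl turned to 0.53 with the wider cell filter, 0.51 without doublet removal, 0.18 at resolution 2 and 0.52 with the hashtag rule, Cd36 to 0.47, 0.41, 0.20 and 0.53, and Mmp12 to 0.42, 0.45, 0.24 and 0.45. Against cDC2-like cells alone Nr1h2 turned to 0.14, Mpc1 to -0.23 and Pgk1 to 0.20. Of the other values for named genes, mice left out included, 4843 kept direction and side of the threshold, 714 no longer passed and 28 newly passed.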

Other observations

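The edgeR tests in classes other than the 3 dendritic ones and in single clusters were chosen only after the data were seen, and the values are given without explanation. The ribosomal repeat transcript AY036118 was at 3491 and 3676 CPM in all cells of the control mice, 4363 and 4365 in the TDLN and 1211 and 1232 in the tumor. Xist had 0 to 3 counts and Ddx3y was at 54.6 to 59.8 CPM in all 6 mice.

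In pDC-like cells 258 genes rose and 287 fell from the control node to the TDLN, with Lyz2 at 307 against 17.0 CPM and Csf1r at 30.7 against 2.29, while Isg15 fell by 1.69. Between tumor and TDLN, Lyz2 fell by 3.17 in these cells and Cd8a rose by 0.80. In macrophage-like cells of the tumor 509 genes rose and 371 fell against the TDLN, with Thbs1 at 128 against 2.12 CPM, Spp1 at 137 against 5.84, Epcam at 143 against 4.58 and Vegfa at 33.7 against 1.49, while Ly6c2 fell by 2.04. The clusters behind this class differed, as cluster 14 held 84.6% and 93.4% of it in the TDLN but 31.5% and 7.84% in the tumor, where clusters 13 and 23 held most, and within cluster 14 only 11 genes rose and 19 fell. In T cell-like cells of the tumor 284 genes rose and 49 fell, among them the mast cell genes Tpsab1 (87.8 CPM), Tpsb2 (70.4 CPM) and Mcpt4 (58.3 CPM), which were listed at 0 in the TDLN. Cluster 21 held 19.0% and 41.0% of this class in the tumor against 9.50% and 6.18% in the TDLN, and within cluster 9, the largest, 27 genes rose and 12 fell. In B cell-like cells 36 genes rose and 50 fell from the control node to the TDLN, with Ccl22 at 43.7 against 2.21 CPM and Ccl5 at 36.1 against 207.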
